A study of Mus musculus with 6 samples.

How the data were processed

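Gene expression was measured by RNA sequencing of total RNA from mouse intestinal epithelial cells. There were 3 libraries from C57BL/6J mice given 450 µg of lipopolysaccharide (LPS, a component of the outer membrane of Gram-negative bacteria) and 3 from mice given phosphate-buffered saline (PBS), with 6 h of treatment in both groups. The mice were 9 weeks and 4 days old. The labels call the libraries of a group biological replicates and do not say which part of the intestine was taken, how the epithelium was isolated, or by which route LPS was given.

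The authors deposited raw counts per gene, 1 column per library, with gene coordinates and gene length, per the file headers, whose layout is that of featureCounts. The submitters' processing notes name FastQC, Trimmomatic 0.28, HISAT2 2.1.0, featureCounts 1.6.1 and DESeq2, and the genome build mm10, without giving their roles or settings. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads of near-identical genes could therefore be lost or split (the Ly6, Reg3, Defa, Gbp, Tgtp, Saa, H2 and Gsdmc families), and reads of overlapping genes on opposite strands could be counted together. Among the genes named, exons of Abcg5, Abcg8, Ace, Axin2, Ccl25, Ciita, Cry2, Csf1r, Cubn, Cxcl10, Cxcl11, Duoxa2, Fgf15, Gbp6, Gbp8, H2-Q4, Heph, Hif1a, Icam1, Il17rb, Lss, Mettl7b, mt-Co1, Mt2, Myd88, Mylk, Nlrc5, Nox1, Nr1d1, Olfm4, Prom1, Psmb8, Psmb9, Ripk1, Slc3a1, Slc51a, Tap1, Tgtp1, Tirap, Tjp3, Trpm5, Vil1 and Zfp36 overlap another annotated gene, so their values are uncertain to that extent. The file held 54838 genes, of which 54723 IDs matched a symbol in the reference table and 115 did not. Start and end equalled those of the GENCODE annotation of the same build for 54123 genes. No column of per-sample values was left unused, and none was pooled.

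Library totals ranged from 11908397 to 20120169 counts. Counts were compared between libraries by chi-square to look for a library deposited more than once. The ratio of chi-square to degrees of freedom was 36.04 or higher for each of the 15 pairs, far above sampling noise, so each library was counted as a separate sample. The p-values of single genes and of shares of counts rest on the spread among 3 libraries per group. Those of gene lists tested with a preset correlation also treat genes as nearly independent. Those of the later comparisons of clock genes and of villus genes count genes, not libraries.

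The test of differential expression was edgeR's quasi-likelihood F-test (edgeR 4.0.16 in R 4.3.3, glmQLFit with robust=TRUE) on the deposited counts with TMM factors and group as the sole term. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 13045 genes holding 99.85% of the counts. P-values were adjusted by the Benjamini-Hochberg method over these genes, with a threshold of 0.05. Adjusted p-values of genes in the text are from this test. Log2 fold changes are LPS against PBS, with standard errors taken from the F statistic. Levels are TMM-scaled CPM (counts scaled to a common library size), as mean ± SD over 3 libraries. For a gene with 0 counts in all libraries of a group, the fold is a bound against 3 counts over that group. For 1 to 3 counts, the ratio has an exact 95% binomial interval. Intervals and bounds cover counting error only.

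The 37 gene lists were fixed before the data were examined. They cover inflammatory, metabolic and epithelial programs, markers of epithelial and other cell types, intestinal regions, the circadian clock, tissue dissociation and the mitochondrial genome. The 35 lists with at least 3 tested genes were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01. Camera asks whether the genes of a list moved more than the other genes. Its p-values were adjusted over the 35 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in a single direction, were run as alternatives. Member counts come from the edgeR test, adjusted over all genes and over the list alone. Shares of counts were compared by an exact two-sided permutation test, whose smallest possible p with 3 against 3 libraries is 0.1.

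The genes to be named were set by a rule written before the data were examined. It took genes with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the libraries of the groups. Of these it named the 5 with the highest and the 5 with the lowest log2 fold change, leaving out pseudogenes, predicted and unnamed genes. It also named the 2 members with the smallest p of each list on biology, called or not where fewer than 2 met the conditions, the member with the highest mean CPM of every other list, and Tlr4, Tnfrsf1a, Ifnar1 and Nr3c1. Other list members named in the text were chosen after their values were seen. The values of a few list members are not reported here.

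The alternatives were DESeq2 1.42.0 and limma-voom as tools, RLE and upper quartile factors and plain library totals as scalings, no filter except on genes without counts, a filter of 1 CPM in 3 libraries, robust=FALSE, the replicate number as a block, the counts without mitochondrial, haemoglobin and immunoglobulin genes, and each library left out in turn. For the lists they also included a prior count of 0.5. A fit without LPS replicate 1 and PBS replicate 3 was added after seeing the data. In simulated counts with the means and library sizes of the real libraries, 33% of 100 genes changed 2-fold and 93% of 100 genes changed 4-fold were recovered. There were 16 false calls among the 13045 genes and 0 changed genes had the wrong sign. Set against the genes recovered, these false calls were a larger share of all calls than the adjusted p threshold aims at.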

Results

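The deposited counts covered 6 libraries of mouse intestinal epithelial cells, 3 from mice treated with LPS for 6 h and 3 from PBS-treated controls, and the series title places the comparison in the study of the inflammatory response to LPS. The LPS libraries held 15167805, 11908397 and 14171715 counts (replicates 1, 2 and 3), and the PBS libraries 13172665, 20120169 and 14234868. Mean totals differed by less than the spread between libraries (exact permutation test, two-sided, p = 0.5). A count of 3 corresponded to between 0.137 and 0.254 CPM, depending on the library.

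The groups separated on the first principal component of log2 CPM, which held 72.1% of the variance. The LPS libraries did not lie together. Replicates 2 and 3 had scores of -67.5 and -76.9, whereas replicate 1 lay at -20.9, between them and the PBS libraries, which had scores of 54.2 to 56.2. On the second component (13.0%), PBS replicate 3 stood apart with a score of -46.4. LPS replicate 1 correlated with the other LPS libraries at 0.969 and 0.958 (Pearson's r across genes, which are not independent replicates) and with the PBS libraries at 0.936 to 0.948.

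**Figure D1:**
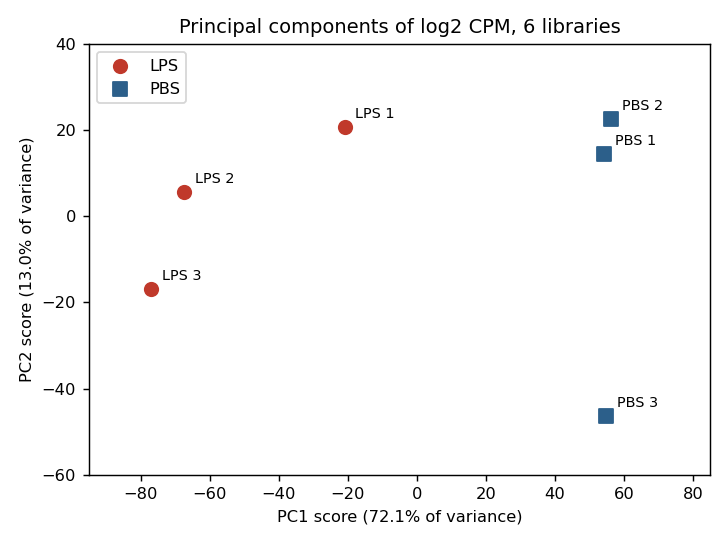
Scores of the 6 libraries on the first (x axis, 72.1% of the variance) and second (y axis, 13.0%) principal components of log2 CPM, without units. Circles are LPS and squares PBS libraries, and LPS replicate 1 lies between its group and the PBS libraries.

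After LPS 1617 genes were higher and 1437 lower than in PBS (3054 of 13045 tested genes, 23.4%). Of these, 1118 were higher and 938 lower by an estimated factor of at least 2. The 5 highest named genes were Ly6g, Ly6c1, S100a9, S100a8 and Cxcl5. Ly6g (ENSMUSG00000022582, mm10 chromosome 15, 75155240 to 75159126) reached 72.6 ± 54.8 CPM under LPS (SD, n = 3) against 0 counts in the PBS libraries, at least 1080-fold higher (adjusted p = 0.00609). Ly6c1 (54.6 ± 35.03 CPM) and S100a8 (34.7 ± 53.0 CPM) were also without counts in PBS, and were at least 827-fold and 529-fold higher. S100a9, which with S100a8 forms calprotectin, stood at 170 ± 235 CPM against 1 count in PBS, a ratio of 7782 (95% interval 1396 to 307400). The neutrophil chemoattractant gene Cxcl5 also had 1 count in PBS, with a ratio of 1266 (226.8 to 50070). The 5 lowest were Aqp3, Tppp, Angptl4, Pck1 and Enpp3. Aqp3, a water and glycerol channel (ENSMUSG00000028435, chromosome 4, 41092722 to 41098183), fell from 12.6 ± 4.36 to 0.355 ± 0.241 CPM (log2 fold change -5.08 ± 0.51 SE, adjusted p = 0.000746). Pck1, the gluconeogenic enzyme, fell from 125 ± 42.0 to 5.46 ± 8.26 CPM (-4.46 ± 1.06 SE, adjusted p = 0.0211), and Tppp, Angptl4 and Enpp3 changed by -5.02, -4.55 and -4.30. In 43.6% of all tested genes the libraries of the groups did not overlap, where chance gives 10%. The same held for 3013 of the 3054 changed genes, a number largely fixed by their selection with the test. The count of changed genes dropped to 1364 without LPS replicate 2, 1537 without LPS replicate 3, 1843 without PBS replicate 1 and 1924 without PBS replicate 2, and rose to 5754 without LPS replicate 1 and PBS replicate 3, a choice made after seeing the data. S100a8 lost its call without LPS replicate 2 (adjusted p = 0.0541) or any PBS library (0.0829, 0.121 and 0.114 without replicates 1, 2 and 3; range over all alternatives 0.000214 to 0.349). It also did so without LPS replicate 1 and PBS replicate 3 (0.306), as did S100a9 (0.214). S100a9 lost it without PBS replicate 3 as well (0.065, range 5.07e-08 to 0.214) and Cxcl5 without PBS replicate 2 (0.0696, range 3.32e-06 to 0.0696). Pck1 lost it without LPS replicate 2 (0.0539), PBS replicate 2 (0.0695) or PBS replicate 3 (0.066, range 2.47e-05 to 0.146). Without the filter S100a8, S100a9, Cxcl5, Pck1, Ly6g, Ly6c1 and Enpp3 lost their calls (0.349, 0.0646, 0.0692, 0.146, 0.141, 0.0977 and 0.0857), as did Enpp3 without LPS replicate 1 and PBS replicate 3 (0.1). The ranges of Ly6g, Ly6c1 and Enpp3 were 1.93e-10 to 0.141, 2.36e-12 to 0.0977 and 6.65e-05 to 0.1. The size of several of these folds rests on single libraries. Without LPS replicate 3 S100a8 was at least 59.3-fold higher, and the ratios of S100a9 and Cxcl5 were 1520 and 469. Without LPS replicate 1 the bounds of Ly6g and S100a8 were 1670 and 865 and the ratios of S100a9 and Cxcl5 12600 and 2040. Without PBS replicate 2 the bounds of Ly6g, Ly6c1 and S100a8 were 596, 456 and 292, and the ratio of S100a9 was 4290. Cxcl5 without PBS replicate 2 and S100a9 without PBS replicate 3 had 0 counts left in PBS and were at least 233-fold and 1940-fold higher. Without LPS replicate 1 the log2 fold changes of Pck1, Tppp and Enpp3 were -7.48, -5.93 and -5.175, and that of Enpp3 without PBS replicate 2 was -3.15. Pck1 was at -5.77 with limma-voom and -5.47 with the replicate number as a block.

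Most genes stimulated by interferon rose. Of 30 genes of the type I interferon list, 29 were higher and 0 lower, with a median log2 fold change of 2.51. Oas2, a sensor of double-stranded RNA, rose from 2.01 ± 0.13 to 42.5 ± 18.6 CPM (log2 fold change 4.39 ± 0.37 SE, adjusted p = 0.000587), and Bst2, the antiviral membrane protein tetherin, rose 5.29-fold. Ifit1 reached 690 ± 211 CPM against 67.0 ± 22.4. Of 21 genes associated with interferon gamma, mainly interferon-inducible GTPases, 17 were higher and 0 lower (median 2.47). Irgm1 rose from 101 ± 19.99 to 722 ± 296 CPM and Tgtp1 by 5.47 ± 0.53 SE on the log2 scale, whereas Gbp6, Gbp8, Ido1 and Ciita did not pass. The numbers adjusted over the list alone were also 29 and 17. Both lists passed camera with the preset correlation (adjusted p = 2.39e-17 and 9.54e-10) and neither passed with an estimated correlation (adjusted p = 0.655 for both).

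Most cytokine and chemokine genes tested rose. Among 20 tested cytokine and chemokine genes, 12 were higher and 2 lower (13 and 2 adjusted over the list alone), with a median of 2.71. Tnf rose from 1.02 ± 0.43 to 11.9 ± 4.85 CPM (log2 fold change 3.55 ± 0.44 SE, adjusted p = 0.00131), and Il33, an alarmin of barrier tissues, from 10.5 ± 5.54 to 271 ± 151 CPM (4.68 ± 0.65 SE, adjusted p = 0.00307). The interferon-induced chemokines Cxcl9, Cxcl10 and Cxcl11 rose by 3.25, 4.35 and 2.88, and Ccl20 by 4.32. The lower members were Il18 (-1.34) and Ccl25 (-1.08), both made by resting epithelium. Il6, Il1a, Il12b, Il23a, Csf2, Csf3, Cxcl2, Cxcl3 and Ccl7 had too few counts to be tested. Of these Cxcl3 had 67 counts under LPS and 1 in PBS, and Ccl7 had 81 and 0, while the counts of the others are not reported here. Cytokine genes as a list passed camera with the preset correlation (adjusted p = 0.00369) and not with an estimated correlation (adjusted p = 0.655). Without LPS replicate 2 or PBS replicate 2, 8 and 9 of its members changed instead of 14, and 18 without LPS replicate 1 and 19 with DESeq2. Cxcl9, Cxcl10, Cxcl11, Ccl20, Il18 and Ccl25 lost their calls in at least 1 of the 6 fits with 1 library left out (adjusted p up to 0.123, 0.0552, 0.097, 0.14, 0.0676 and 0.0509). In these fits the log2 fold changes ranged from 2.69 to 4.22 for Cxcl9, 3.82 to 4.98 for Cxcl10, 2.28 to 3.38 for Cxcl11 and 2.097 to 4.88 for Ccl20.

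The NF-kB list did not pass as a set (camera adjusted p = 0.139), although 7 of 20 members rose and 1 fell (8 and 2 adjusted over the list alone, median 0.29). Socs3, an inhibitor of cytokine signalling, rose from 59.5 ± 26.1 to 563 ± 114 CPM (log2 fold change 3.24 ± 0.34 SE, adjusted p = 0.000785), and the adhesion molecule Icam1 rose by 4.83 ± 0.64 SE. The inhibitors of NF-kB signalling Nfkbia, Tnfaip3, Zc3h12a and Tnip3 rose by 1.70, 1.53, 1.14 and 5.48, and the subunit gene Rel by 1.31, while the subunit gene Relb fell by 1.39. The list passed without LPS replicate 1 (adjusted p = 0.0172) and without LPS replicate 1 and PBS replicate 3 (0.00684), with a range of 0.00684 to 0.848 over the alternatives. Its count of changed members was 4 instead of 8 without LPS replicate 2, LPS replicate 3, PBS replicate 2 or PBS replicate 3, and 5 without PBS replicate 1. It was 11 without LPS replicate 1 and 13 without LPS replicate 1 and PBS replicate 3. Nfkbia, Tnfaip3, Zc3h12a and Rel kept their calls in 1 of the 6 fits with 1 library left out (adjusted p up to 0.0734, 0.084, 0.144 and 0.122), and Tnip3 ranged from 4.43 to 6.00.

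Of 21 antimicrobial and acute-phase genes 11 were higher and 0 lower (12 and 1 adjusted over the list alone, median 1.71). Lcn2, which binds bacterial siderophores (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252), rose from 0.625 ± 0.183 to 420 ± 314 CPM (log2 fold change 9.36 ± 0.78 SE, adjusted p = 0.000625). Its levels in LPS replicates 1, 2 and 3 were 130, 375 and 754 CPM, and its log2 fold change without replicate 3 was 8.63. Hamp, the iron-regulating peptide hepcidin, rose from 0.406 ± 0.083 to 33.1 ± 19.9 CPM, Saa3 rose by 7.09 and complement C3 by 3.91 (5.20 to 7.62 and 3.26 to 4.81 with 1 library left out). The hydrogen peroxide-producing oxidase Duox2 rose from 493 ± 72.5 to 2337 ± 486 CPM, and its maturation factor Duoxa2 by 2.78 ± 0.37 SE. The abundant lectin genes Reg3b and Reg3g had log2 fold changes of 0.59 ± 0.52 and 0.86 ± 0.44 SE and did not pass. Camera with the preset correlation called the list (adjusted p = 5.03e-06) and not with an estimated correlation (adjusted p = 0.655).

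Among 28 receptors and adaptors for LPS and cytokines, 10 were higher and 0 lower (12 and 2 adjusted over the list alone, median 0.34). The adaptor Tirap rose 2.83-fold to 32.8 ± 3.53 CPM (adjusted p = 0.0011) and the TNF receptor gene Tnfrsf1b 5.12-fold to 64.2 ± 23.8 CPM (adjusted p = 0.00134). The LPS co-receptor Cd14, Tlr2 and Myd88 rose by 2.38, 2.62 and 1.69. Tnfrsf1a was 190 ± 46.2 CPM in PBS and 513 ± 144 CPM under LPS (log2 fold change 1.43 ± 0.27 SE, adjusted p = 0.00706). The LPS receptor gene Tlr4 had 1.51 ± 0.94 and 3.62 ± 0.67 CPM (1.29 ± 0.47 SE, adjusted p = 0.077), so that it did not pass, except without PBS replicate 1 (0.0415), with limma-voom (0.0482) or without the filter (0.0213; range over the alternatives 0.0213 to 0.21). The interferon receptor gene Ifnar1 had a log2 fold change of 0.15 ± 0.17 SE (adjusted p = 0.551). The list passed camera with the preset correlation (adjusted p = 0.0038) and not with an estimated correlation (adjusted p = 0.655).

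**Figure D2:**
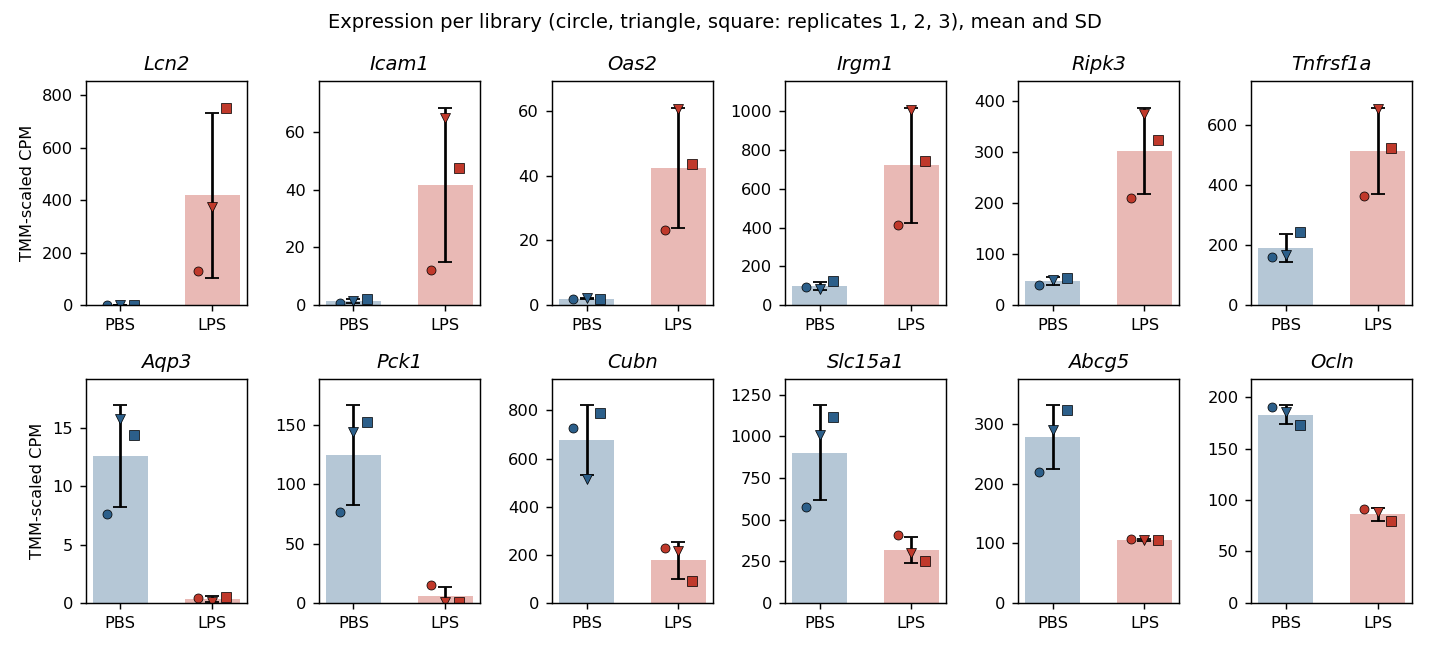
TMM-scaled CPM (y axes, linear from 0) of 12 named genes in the PBS and LPS libraries. Bars are means of 3 libraries, error bars SD and symbols single libraries; LPS replicate 1 (circle) is the lowest LPS library for Lcn2, Icam1, Oas2, Irgm1, Ripk3 and Tnfrsf1a, while Abcg5 lies at 106 ± 1.62 CPM under LPS.

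Of 28 genes of apoptosis, pyroptosis and necroptosis, 7 were higher and 2 lower (8 and 2 adjusted over the list alone, median 0.57). The kinase gene Ripk3 rose from 47.4 ± 7.82 to 303 ± 84.5 CPM (log2 fold change 2.67 ± 0.26 SE, adjusted p = 0.000665) and its substrate Mlkl, the executioner of necroptosis, from 16.3 ± 2.05 to 115 ± 40.04 CPM (2.83 ± 0.29 SE, adjusted p = 0.000747). Zbp1, Casp4, Casp12, Pmaip1 and Tnfsf10 rose by 1.47, 1.67, 2.22, 2.06 and 1.41, and Gsdmc3 and Nlrp6 changed by -1.52 and -1.09. The other 19 genes did not pass, among them the kinase gene Ripk1 (0.638, adjusted p = 0.0871). Camera with the preset correlation called the cell death list (adjusted p = 0.0343), but not with an estimated correlation (adjusted p = 0.734). It also lost its call with fry (0.0795) and without LPS replicate 2 (0.0521), LPS replicate 3 (0.0933), PBS replicate 1 (0.0918) or PBS replicate 2 (0.0523), with a range of 0.00403 to 0.734 over the alternatives. Zbp1, Casp4, Gsdmc3 and Nlrp6 lost their calls in at least 1 of the 6 fits with 1 library left out (adjusted p up to 0.0528, 0.0992, 0.0561 and 0.134).

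MHC class I genes rose in part and class II genes did not pass. Of 18 class I genes, 5 were higher and 0 lower (6 adjusted over the list alone, median 0.55). The peptide transporter gene Tap1 rose from 161 ± 45.0 to 513 ± 160 CPM, the class I transactivator Nlrc5 rose 3.26-fold, and Psmb8, Psmb9 and H2-Q4 rose by 0.81, 0.76 and 1.11, with calls in 2 of the 6 fits with 1 library left out (adjusted p up to 0.0998, 0.143 and 0.119). The list passed camera with the preset correlation (adjusted p = 0.0038) and not with an estimated correlation (adjusted p = 0.734) or with fry (0.151). Of 9 class II genes 0 passed with edgeR, DESeq2 or limma-voom or over the list alone, and 1 had an unadjusted p under 0.05 (edgeR; median -0.42, camera adjusted p = 0.225). H2-Aa stood at 1212 ± 547 CPM in PBS and 781 ± 89.8 CPM under LPS, and H2-DMa at 101 ± 37.2 and 67.7 ± 2.73 CPM.

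Of 21 brush-border enzymes and transporters, 13 were lower and 0 higher (15 lower adjusted over the list alone), with a median log2 fold change of -1.09. Cubn, the vitamin B12-intrinsic factor receptor, fell from 677 ± 144 to 178 ± 76.5 CPM (-1.93 ± 0.36 SE, adjusted p = 0.00641, and 0.0667 without LPS replicate 1 and PBS replicate 3), and the peptide transporter gene Slc15a1 from 901 ± 286 to 319 ± 78.4 CPM (-1.50 ± 0.30 SE, adjusted p = 0.00874). The abundant aminopeptidase gene Anpep went from 13957 to 4729 CPM, sucrase-isomaltase Sis from 3853 to 1288 CPM, and the sugar transporter genes Slc5a1, Slc2a2 and Slc2a5 changed by -1.09, -3.95 and -2.32. Fabp2, Vil1, Lct, Mgam, Enpep, Ace, Slc7a9 and Slc3a1 did not pass. The list passed camera with the preset correlation (adjusted p = 2.84e-06) and not with an estimated correlation (adjusted p = 0.655). Its count of lower members was 4 without LPS replicate 2, 5 without LPS replicate 3 and 8 without PBS replicate 3. Anpep, Sis, Slc5a1 and Slc2a5 lost their calls in at least 1 of the 6 fits with 1 library left out (adjusted p up to 0.0697, 0.0588, 0.126 and 0.107), and Slc2a2 and Slc2a5 ranged from -5.07 to -3.44 and from -3.23 to -1.87.

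Of 23 xenobiotic genes, 9 were lower, 0 higher and 14 not called, with the same numbers lower and higher over the list alone (median -0.76). The glucuronosyltransferase genes Ugt2b34 and Ugt2b5 changed by -1.39 ± 0.22 and -2.41 ± 0.47 SE, to 251 ± 39.6 and 2.14 ± 1.24 CPM. Of 21 lipid absorption genes, 4 were lower, 0 higher and 17 not called (7 lower and 1 higher adjusted over the list alone, median -0.46). The lower genes were the cholesterol uptake transporter Npc1l1 (-1.48), the sterol efflux transporters Abcg5 and Abcg8 (-1.39 ± 0.20 and -1.35 ± 0.20 SE, adjusted p = 0.00221 and 0.00275) and Plin3 (-0.96, adjusted p up to 0.143 with 1 library left out). Both lists passed camera with the preset correlation (adjusted p = 0.000723 and 0.0217) and not with an estimated correlation (adjusted p = 0.655 and 0.83) or with fry (0.088 and 0.194). The lipid list also lost its call without LPS replicate 3 (0.0951), PBS replicate 2 (0.0523) or PBS replicate 3 (0.0566), with a range of 0.000599 to 0.83 over the alternatives.

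Fatty acid oxidation and cholesterol synthesis genes went both ways. Of 22 fatty acid oxidation genes 5 were lower and 1 higher (7 and 1 adjusted over the list alone, median -0.26, camera adjusted p = 0.225). The peroxisomal enzyme gene Ehhadh fell from 113 ± 21.1 to 41.5 ± 8.65 CPM (-1.45 ± 0.22 SE, adjusted p = 0.00297), with Acads, Cpt2, Acadm and Hadh at -1.02, -0.92, -0.84 and -0.83. Acadl, the long-chain acyl-CoA dehydrogenase, rose from 123 ± 51.5 to 520 ± 37.9 CPM (2.08 ± 0.31 SE, adjusted p = 0.00275). Of 20 cholesterol synthesis genes 3 were lower, among them Dhcr7 (-1.32 ± 0.25 SE) and Stard4 (-0.96 ± 0.20 SE), and Lss was higher (0.81), with the same counts over the list alone. Its median was 0.03 and its mean -0.07, and it did not pass (camera adjusted p = 0.836). Stard4 lost its call without LPS replicate 2 (adjusted p = 0.0515, range over the alternatives 5.36e-05 to 0.0515), and Cpt2, Hadh and Lss in 4 of the 6 fits with 1 library left out (adjusted p up to 0.13, 0.127 and 0.111).

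**Figure D3:**
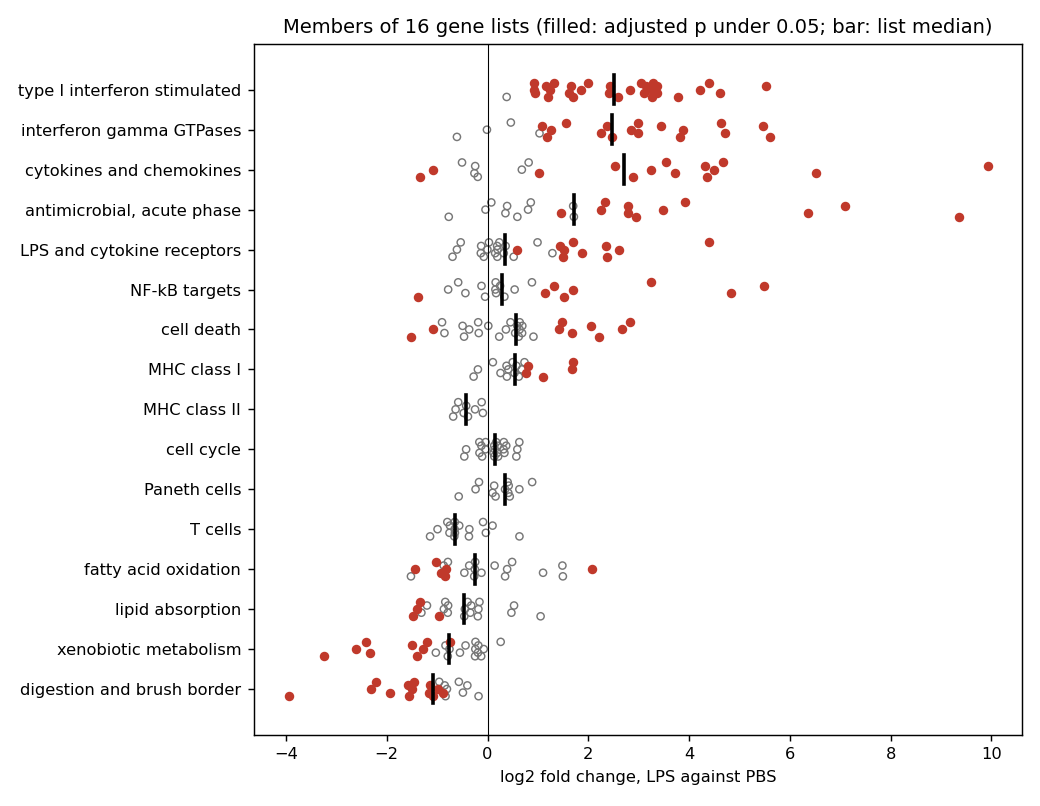
Log2 fold change, LPS against PBS (x axis), of the tested members of 16 gene lists (y axis). Filled points passed an adjusted p of 0.05, open points did not, and bars are list medians, such as 2.51 for the type I interferon list and -1.09 for the digestion list.

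Among 21 junction genes 3 were higher and 4 lower (4 and 5 adjusted over the list alone, camera adjusted p = 0.977), and their median (0.22) and camera direction differed in sign. Occludin (Ocln) fell from 183 ± 9.24 to 86.1 ± 6.17 CPM (log2 fold change -1.09 ± 0.16 SE, adjusted p = 0.00284) and the myosin light chain kinase gene Mylk from 157 ± 16.1 to 55.1 ± 11.2 CPM (-1.51 ± 0.20 SE, adjusted p = 0.00171). Cldn15 and Tjp3 fell by 2.29 and 0.79, and Cldn1, Cldn12 and Cdh1 rose by 2.94, 1.11 and 0.89. Cldn15, Tjp3, Cldn12 and Cdh1 lost their calls in at least 1 of the 6 fits with 1 library left out (adjusted p up to 0.0565, 0.128, 0.0913 and 0.121), and Cldn15 and Cldn1 ranged from -3.20 to -1.96 and from 2.36 to 3.75. Of 15 glucocorticoid response genes 6 were higher and 1 lower, over all genes and over the list alone (median -0.06, mean 0.28, camera adjusted p = 0.681). Metallothionein Mt2 rose 3.10-fold and Angptl4, also a PPAR target, fell 23.5-fold to 4.68 ± 2.17 CPM. The receptor gene Nr3c1 had 195 ± 4.96 and 143 ± 24.8 CPM in PBS and LPS (adjusted p = 0.109, 0.0363 without LPS replicate 1 and 0.0147 without LPS replicate 1 and PBS replicate 3, range over the alternatives 0.0147 to 0.335). Of 19 endoplasmic reticulum stress genes 4 were higher (Xbp1, Atf4, Trib3 and Chac1) and Ern1 was lower (4 and 2 adjusted over the list alone, median 0.23, camera adjusted p = 0.52). Xbp1 rose 2.01-fold and Ern1, the kinase that splices its transcript, fell 1.89-fold, and each lost its call without LPS replicate 2, LPS replicate 3, PBS replicate 1 or PBS replicate 2 (adjusted p up to 0.0559 for Xbp1 and 0.13 for Ern1). Ern1 lost it with library totals as scaling too (0.0815), and Atf4, Trib3 and Chac1 with 1 library left out (adjusted p up to 0.16, 0.126 and 0.109).

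Markers of epithelial cell types other than enterocytes gave few calls. Of 23 cell cycle genes 0 passed with edgeR, DESeq2 or limma-voom or over the list alone, and 1 had an unadjusted p under 0.05 (median 0.14, camera adjusted p = 0.324), with Rrm2 at 18.8 ± 5.93 and 29.1 ± 5.57 CPM and Ccne1 at 4.47 ± 0.86 and 6.75 ± 1.58 CPM in PBS and LPS. Of 13 Paneth cell genes 0 passed with edgeR (1 at an unadjusted p under 0.05) or limma-voom and 1 with DESeq2 (0 over the list alone, median 0.35, camera adjusted p = 0.381), with Lyz1 at 6436 ± 2726 and 8563 ± 1880 CPM. Of 15 stem and crypt genes Cd44 and Prom1 were higher (1.96 and 0.79) and Axin2 lower (-1.11), and Olfm4 had a log2 fold change of -0.16 ± 0.36 SE (median 0.12, camera adjusted p = 0.673). Of 12 goblet cell genes Clca1 and Atoh1 were lower (-0.83 and -1.41, with 0 adjusted over the list alone), and Zg16 was 3991 ± 1220 and 3033 ± 355 CPM (median -0.39, camera adjusted p = 0.118, and 0.047 without the filter, range over the alternatives 0.047 to 0.655). Of 13 enteroendocrine genes Cck was higher (1.72), and Nts stood at 124 ± 63.5 and 128 ± 18.6 CPM (median 0.26, camera adjusted p = 0.235). Of 9 tuft cell genes Il17rb was lower (-2.07), and Trpm5 stood at 19.3 ± 8.21 and 17.7 ± 10.2 CPM (median -0.13, camera adjusted p = 0.977). Prom1, Axin2, Clca1, Atoh1 and Il17rb lost their calls in at least 1 of the 6 fits with 1 library left out (adjusted p up to 0.0851, 0.0574, 0.169, 0.142 and 0.0625), Clca1 in each of them, and Atoh1 ranged from -2.17 to -1.11.

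Markers of other cells moved with the groups in several lists, each through a few genes. Of 4 tested neutrophil genes S100a8, S100a9 and Ly6g were higher, while Csf3r, Cxcr2, Mmp8, Mmp9, Retnlg, Ngp, Camp, Trem1 and Padi4 had too few counts to be tested (camera adjusted p = 0.00865, and adjusted p = 0.655 with an estimated correlation). The median log2 fold change of the tested genes was 12.3, and 9.56 with Ly6g and S100a8 at their bounds. S100a8, S100a9 and Ly6g had 0 or 1 counts in PBS and passed the filter only through the LPS libraries. Their direction, the median and the camera result were thus largely fixed by the filter. The list also lost its call without the filter (adjusted p = 0.0857, range 0.00217 to 0.655 over the alternatives). S100a9 was 8.12, 62.6 and 440 CPM in LPS replicates 1, 2 and 3. Of 12 B and plasma cell genes Igha, Igkc and Jchain were higher, over all genes and over the list alone (median 0.91). Igha rose 7.72-fold, from 118 ± 31.0 to 911 ± 687 CPM (adjusted p = 0.00933, 0.062 without PBS replicate 3 and 0.0946 without the filter, range over the alternatives 5.7e-08 to 0.0946), and Igkc and Jchain by 2.85 and 2.82. Without LPS replicate 2 the log2 fold change of Igha was 2.22 (2.95 with all libraries), and Igkc had an adjusted p of up to 0.0537 with 1 library left out. These genes passed camera with the preset correlation (adjusted p = 0.0343) and not with an estimated correlation (adjusted p = 0.707). They also lost the call without mitochondrial, haemoglobin and immunoglobulin genes (0.133), with fry (0.146), and without LPS replicate 3 (0.133), PBS replicate 1 (0.0631), PBS replicate 3 (0.137) or LPS replicate 1 and PBS replicate 3 (0.0642), with a range of 0.000883 to 0.707 over the alternatives. Immunoglobulin genes took 0.186 ± 0.130% of the counts under LPS and 0.0281 ± 0.0098% in PBS (exact permutation test, two-sided, p = 0.1, the smallest possible). Of 10 macrophage and dendritic cell genes the mannose receptor gene Mrc1 was higher (65.2 ± 30.1 against 5.07 ± 2.58 CPM, log2 fold change 3.71 ± 0.46 SE) and Csf1r and Itgax lower (-1.68 and -1.55; median -0.50, camera adjusted p = 0.139), Itgax with an adjusted p of up to 0.0536 with 1 library left out. Of 5 endothelial genes Tie1 was higher (27.4 ± 3.94 against 2.89 ± 1.85 CPM, log2 fold change 3.29, and 3.875 without PBS replicate 3; median 0.63, camera adjusted p = 0.225), and of 12 stromal genes Dcn was higher (36.2 ± 21.3 against 8.16 ± 6.32 CPM, log2 fold change 2.17, 1.58 without LPS replicate 3 and 2.99 without PBS replicate 3; median 0.07, camera adjusted p = 0.875). Dcn lost its call without LPS replicate 3, PBS replicate 1 or PBS replicate 2 (adjusted p = 0.0851, 0.0843 and 0.0963) or without the filter (0.172, range over the alternatives 0.000258 to 0.172), and did not pass over the list alone.

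Of 16 T cell genes 0 passed with edgeR (4 at an unadjusted p under 0.05) or limma-voom and 2 with DESeq2 (0 over the list alone, median -0.65, camera adjusted p = 0.12). The list passed, downwards, without the filter (adjusted p = 0.047), PBS replicate 1 (0.0409) or PBS replicate 2 (0.0108), and ranged from 0.0108 to 0.851 over the alternatives. Gzma was 475 CPM in PBS replicate 3 against 183 and 151 CPM in PBS replicates 1 and 2, and 289 ± 63.2 CPM under LPS. It was called higher without PBS replicate 3 (log2 fold change 0.785, adjusted p = 0.0491) and without LPS replicate 1 and PBS replicate 3 (0.866, adjusted p = 0.00426). Of the red blood cell genes 2 were tested and 0 passed with edgeR, DESeq2 or limma-voom or at an unadjusted p under 0.05, Hbb-bs being 2.71 ± 2.06 CPM under LPS and 1.20 ± 0.92 CPM in PBS. Of the exocrine pancreas genes only Cela1 was tested (log2 fold change -0.26 ± 0.31 SE). Haemoglobin genes took 0.000482 ± 0.000329% and 0.000219 ± 0.000189% of the counts (exact permutation p = 0.3). The 10 most counted genes took 11.8 ± 3.06% and 10.5 ± 1.99% (p = 0.5), and mitochondrial genes 4.67 ± 1.76% and 3.80 ± 0.67% (exact permutation p = 0.6). Both of these last differences changed sign without LPS replicate 3. Of 10 mitochondrial genes 0 passed with edgeR, DESeq2 or limma-voom or at an unadjusted p under 0.05 (median 0.48, camera adjusted p = 0.235, and 0.0103 without LPS replicate 1 and PBS replicate 3, range over the alternatives 0.0103 to 0.907), with mt-Co1 at 17729 ± 8081 and 14605 ± 5079 CPM.

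The regional lists did not pass. Of 9 ileal genes Fgf15, Slc51a and Mep1a were lower (-2.73, -1.35 and -1.17; median -0.47, camera adjusted p = 0.24, and 0.0114 without PBS replicate 2, range 0.0114 to 0.851 over the alternatives). Of 8 proximal genes Adh6a was higher (1.77; median -0.60, adjusted p = 0.977). Of 5 large intestinal genes Car4 and Aqp4 were higher and 2 were lower, among them Mettl7b (2 and 3 adjusted over the list alone, camera adjusted p = 0.535). Fabp6, the ileal bile acid binding protein, was 7117, 2289 and 10410 CPM in PBS replicates 1, 2 and 3, and Lct, highest in the proximal intestine, was 78.8, 673 and 103 CPM. Under LPS Fabp6 was 4781 ± 1134 CPM. Heph was 562 ± 125 CPM in PBS and 390 ± 16.4 CPM under LPS (adjusted p = 0.102, and 0.048 with library totals as scaling). Fgf15, Slc51a, Mep1a and Adh6a lost their calls in at least 1 of the 6 fits with 1 library left out (adjusted p up to 0.0722, 0.0933, 0.09 and 0.0503), and Fgf15 ranged from -3.40 to -2.32. Car4 rose 5.04-fold (log2 fold change 2.33, and 1.56 without LPS replicate 3) and lost its call without PBS replicate 1 or PBS replicate 2 (adjusted p = 0.0585 and 0.0541) or without the filter (0.106, range over the alternatives 5.39e-06 to 0.106).

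The clock list passed camera, downwards, with the preset correlation (adjusted p = 0.0343) and not with an estimated correlation (adjusted p = 0.707). Of its 13 genes 3 were lower, 1 was higher and 9 were not called, with the same numbers lower and higher over the list alone (median -0.61). Clock itself fell from 79.8 ± 3.58 to 45.3 ± 3.02 CPM (log2 fold change -0.82 ± 0.16 SE, adjusted p = 0.00754), Cry2 and Nr1d1 changed by -2.24 and -1.51, and Ciart by 2.20. The list also lost its call with fry (adjusted p = 0.123), with the replicate number as a block (0.0625), without LPS replicate 3 (0.0951) and without PBS replicate 3 (0.127), with a range of 0.00216 to 0.707 over the alternatives. Nr1d1 and Ciart kept their calls in 2 of the 6 fits with 1 library left out (adjusted p up to 0.15 and 0.109), with log2 fold changes of -2.19 to -1.19 and 1.74 to 2.83. Of 13 immediate early and heat shock genes, which tissue dissociation induces, Hspb1 and Dnajb1 were higher (2.27 and 1.09) and Fosb and Hspa1b lower (median -0.58, camera adjusted p = 0.139, 0.0298 without the filter and 0.0496 without PBS replicate 2, range over the alternatives 0.0298 to 0.734). Fosb had 284 counts in PBS and 1 under LPS, and Zfp36, the most abundant member, was 196 ± 39.2 and 224 ± 19.6 CPM.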

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

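The fit without LPS replicate 1 and PBS replicate 3 was chosen after seeing the data, and the cause of the changes below was not tested. Of 67 named genes 48 were called, and 34 of these kept their direction and call under all 17 alternatives run for genes. The other 14 lost the call under at least 1, and 0 changed sign. Of 192 called members of the lists 109 kept the call in each of the 6 fits with 1 library left out, 83 lost it in at least 1, 33 moved by over 1.5 times and 0 changed sign. Of 35 lists 13 were called, and 0 kept the call under all 19 alternatives. With an estimated correlation 0 lists were called, the type I interferon, cytokine and digestion lists each having an adjusted p of 0.655, and with fry 5 were called (cytokine 0.0668, digestion 0.0795). The count of changed genes ranged from 1364 to 4376 with 1 library left out (higher 821 to 2222, lower 543 to 2154, at least 2-fold 1287 to 3005). Without LPS replicate 1 and PBS replicate 3 it was 5754 (2885 higher, 2869 lower, 3197 at least 2-fold), and the NF-kB list had an adjusted p of 0.00684. With 1 library left out the NF-kB list ranged from 0.0172 to 0.295 and the count of called lists from 9 to 14. Other tools, scalings and filters gave between 2458 and 3669 changed genes, and no scaling moved the median of all genes by over 0.1. With the replicate number as a block 3506 genes changed (1821 higher, 1685 lower), and the clock list had an adjusted p of 0.0625. Whether the numbers pair the samples stays undecided with 3 libraries per group. Once group means were removed, r was 0.0825, 0.0743 and 0.28 for equal numbers, and -0.255 to 0.163 for unequal ones. LPS replicate 1 correlated better with PBS replicate 2 (0.163) than with its own number.

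All results that changed direction were uncalled in the main test. The junction list turned with upper quartile factors (adjusted p = 0.998), library totals (0.915), no filter (0.987) and the block (0.863), the proximal list with library totals (0.983) and no filter (0.987), and the tuft list with the 1 CPM filter (0.976). Without LPS replicate 1 and PBS replicate 3, the cholesterol, cell cycle and stem lists (0.274 each) and the junction (0.52), Paneth (0.503) and tuft (0.645) lists turned, and the log2 fold changes of Trpm5 (0.62), Cela1 (0.18) and Fabp6 (0.16) changed sign. In that fit Nts (0.624, adjusted p = 0.0201), Hbb-bs (2.25, adjusted p = 0.0245) and Gzma (0.866, adjusted p = 0.00426) were called higher. The log2 fold changes of Icam1 (5.545), Il33 (5.28), Tgtp1 (6.07), Nlrc5 (2.31), Mrc1 (4.43), Dcn (3.26), Tie1 (3.98) and Car4 (3.05) were over 1.5 times higher as folds than with all libraries.

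With 1 library left out, adjusted p-values of lists whose direction turned ranged from 0.245 to 0.754 (cholesterol), 0.726 to 0.939 (junctions), 0.56 to 0.939 (tuft), 0.487 to 0.896 (stroma), 0.71 to 0.923 (proximal), 0.37 to 0.969 (large intestine), 0.0582 to 0.487 (cell cycle), 0.245 to 0.873 (stem) and 0.0797 to 0.637 (Paneth). The log2 fold changes ranged from -0.62 to 0.25 for Trpm5, -0.23 to 0.53 for Nts, -0.19 to 0.78 for Gzma, -0.15 to 0.58 for mt-Co1, -0.51 to 0.13 for Olfm4, -0.47 to 0.01458 for Cela1 and -0.88 to 0.01824 for Fabp6. The difference in mitochondrial share ranged from -0.1195 to 1.54 percentage points, that of the 10 most counted genes from -0.538 to 2.37, and that of library totals from -3428000 to 45330 counts. A count of 3 was between 0.137 and 0.254 CPM, and why genes fell under the filter was not tested. Camera was not run on the DESeq2 fit, where members were only counted.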

Other observations

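The gene families of the next sentences, the genes named from them, and the tests of Ly6a reads, neutrophils, mixing, depth, time of day, villus tips and scaling were chosen after the result was seen. Of 10 tested NADPH oxidase genes 8 were higher and 0 lower (median log2 fold change 1.55, camera adjusted p = 3.91e-05 over 9 families, and adjusted p = 0.314 with an estimated correlation). Nox1, a superoxide-producing oxidase, rose from 2.96 ± 1.36 to 104 ± 46.3 CPM (SD, n = 3; log2 fold change 5.09 ± 0.49 SE, edgeR adjusted p = 0.000747). The hypoxia-inducible factor genes Hif1a and Epas1 rose by 3.43 and 2.24 and hexokinase Hk2 by 3.05, while of 16 glycolysis genes 5 were higher and 1 lower (camera adjusted p = 0.0918). Rasd1, a Ras-related G protein induced by glucocorticoids, had the smallest p of all genes (161.7 ± 39.5 against 2.07 ± 0.40 CPM, log2 fold change 6.29 ± 0.29 SE, edgeR adjusted p = 4.05e-05).

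Of 252 solute carrier genes 69 were lower and 29 higher (median -0.38, camera adjusted p = 0.00109, and 0.325 with an estimated correlation), and of 28 cytochrome P450 genes 11 were lower and 1 higher (9.07e-05 and 0.329). Among 79 ribosomal protein genes 21 were higher and 0 lower (median 0.58, 3.25e-11 and 0.343), and among 38 proteasome genes 9 and 0 (1.76e-05 and 0.343). Among 52 immunoglobulin genes 28 were higher and 0 lower (1.14e-08 and 0.325), and among 5 Ly6 genes 5 and 0 (1.06e-05 and 0.314). Ly6g and Ly6c1 had 0 counts in PBS and passed the filter only through the LPS libraries, which fixed their direction in the Ly6 family. A list of 19 markers of repairing or fetal-like epithelium, of which 16 were tested, was written as a hypothesis with its prediction before its values were seen. Of these 9 were higher and 2 lower (median 1.22), and camera gave an unadjusted p of 0.000786 with the preset correlation and 0.239 with an estimated correlation. The list was run again after 2 members had been matched to older symbols, which made its p larger, and it shares Cd44 with the stem list. A repair-like state of the epithelium may account for this rise, but the call rests on the preset correlation.

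S100a8, S100a9, Ly6g and Ly6c1 rose from 0 or 1 counts. Reads of Ly6a counted on Ly6g and Ly6c1 were argued against, since their ratio to Ly6a under LPS gave 94.2 expected counts in the PBS libraries, where 0 were observed. Neutrophils cannot be told apart from other sources in any LPS library. Of 20 other neutrophil transcripts 8 had enough counts to be tested, of which 2 were higher and 1 lower, and no neutrophil profile was measured. The summed level of the 13 of them with under 1 CPM in PBS rose over the lowest PBS library by at most 0.261% of that of S100a8 and S100a9 in LPS replicates 2 and 3 and by 16.2% in LPS replicate 1. Of the 7 transcripts left out of that sum, Ltf and Cd177 were higher under LPS (log2 fold change 2.33 and 1.31, edgeR adjusted p = 0.00983 and 0.0398) and Msrb1 was lower (-0.83). Ltf and Cd177 together rose over the highest PBS library by 183%, 33.5% and 6.89% of S100a8 and S100a9 in LPS replicates 1, 2 and 3. S100a8 and S100a9 together stood at 9.11, 69.8 and 536 CPM there, so Ltf and Cd177 did not rise in proportion to them. Expression by the epithelium and cells of another type both stay open.

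LPS replicate 1 lay between the groups. Mixing with RNA of PBS cells was argued against as the whole cause. Each gene's change from PBS in LPS replicate 1 was taken as a share of its change in the other LPS libraries. Genes that rose at least 4-fold in those libraries had a median share of 0.331 (682 genes) and genes that fell 0.755 (464 genes). The difference was 0.424 (95% bootstrap interval over genes 0.384 to 0.459), where mixing alone gives 1 share. The interval treats genes as independent and does not cover the spread among libraries. Mixing together with another cause can give unequal shares, and the value cannot decide on it. The depth of LPS replicate 1 was not the lowest, with 15167805 counts against 11908397 in LPS replicate 2. Another time of day stays open and cannot be told apart from chance by the number of genes: 5 of 13 clock genes (38.5%) lay outside the range of the other 5 libraries, against 19.0% of other genes (Fisher's exact test, two-sided, p = 0.0835). Of these Arntl (20.95 CPM) and Npas2 (26.1 CPM) lay below that range and Per1, Per2 and Per3 (17.5, 18.5 and 3.66 CPM) above it, and the Per genes are known to peak when Arntl is low, a direction that the test does not use. A slower or weaker response of this mouse was not tested.

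Of 21 digestion and brush border genes 13 were lower and 0 higher (camera adjusted p = 2.84e-06, adjusted p = 0.655 with an estimated correlation and 0.0795 with fry). The 21 members differed by more than their standard errors (heterogeneity chi-square of 3.11 per degree of freedom, a measure that treats genes as independent). A wrong scaling factor moves the members alike. So does a lower share of enterocytes, if all enterocytes and no other cells express the members alike. The value argued against either as the source of the differences among the members. It stays the same when all members move by a common amount. It therefore cannot decide whether either made the common fall (weighted mean log2 fold change -1.04). A loss of some enterocytes, such as those of a villus zone, can move the members unevenly, and the value cannot decide on it. Of 3 other scalings none decided, since they moved the median of all genes by at most 0.0466, against a median of -1.09 for the digestion list. Loss of villus tips cannot be told apart from other causes. A set of 12 tip genes had a median of -0.45 and 11 genes of the middle -1.09 (difference 0.643, permutation test over genes, two-sided, p = 0.254). The middle genes include Slc5a1, Slc2a2, Slc2a5, Slc15a1, Slc7a9 and Slc3a1 of the digestion list itself. Their median thus holds part of the fall to be explained, and the comparison cannot decide. Lower expression per cell may account for the fall and was not tested.

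The 10 splits of the 6 libraries into groups of 3 are too few for a share under 0.05. Every split other than the real one mixes LPS and PBS libraries within both of its groups. Such a split keeps part of the treatment difference, which can still call lists. It also adds that difference to the spread within groups, which lowers the count of changed genes. The values below are thus no measure of what chance gives, and no conclusion is drawn from them. The real split gave 3054 changed genes and 2056 at least 2-fold, and the highest other split 0 of each, so that 1 split gave as many. For called lists the real split gave 13 and the highest other, LPS replicate 1 with PBS replicates 1 and 3, gave 19, and 6 splits gave 13 or more. The smallest adjusted p of another split was 3.76e-12 for the type I interferon list (real 2.39e-17, 1 split as small), 0.000164 for NF-kB (0.139, 6 splits), 0.000782 for cytokines (0.00369, 2 splits) and 9.76e-10 for digestion (2.84e-06, 3 splits).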
